A study of Macaca mulatta with 23 samples.

How the data were processed

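Total RNA of sorted CD8+ TEM from 12 rhesus macaques was measured on 23 Illumina bead arrays, 6 before and 6 after the IgG1 control antibody, and 5 before and 6 after anti-IL-15. Per the labels' protocols, RNA was extracted with a blood RNA kit, only samples above a quality threshold were carried on, input was normalised before amplification, and the biotin-labelled product was hybridised and scanned by Illumina's direct method. The same RNA mass entered each amplification whatever the number of cells, so levels are relative to total RNA and not per cell. The array design names human genes and was applied to macaque RNA, so a probe that mismatches the macaque transcript can read low for that reason alone.

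The deposited signal table holds 1 intensity per probe and array on a linear scale, neither background-subtracted nor normalised, with array medians of 92 to 104, and a value of 0 stood for 9 probes on some array. The deposited table also gives a detection p-value of each probe against the negative control beads of its array. A second table deposited by the authors holds log2 intensities, and the values themselves show quantile normalisation without background subtraction. The submitters' processing notes name limma, and its version is not given in the sources used here. Scale and direction of that table follow from its match to the signals, it was not centred by gene, and it was used as an alternative.

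The intensities were corrected by the normexp model with negative controls inferred from the detection p-values, given an offset of 16, quantile normalised and put on the log2 scale with the neqc function of limma 3.58.1 in R 4.3.3. Probes with a detection p under 0.05 on at least 5 arrays were kept, 15744 of 47230. Of these 11131 had 1 gene symbol, 1 had several and 4612 had none in the annotation table. For a gene with several kept probes, which held for 1660 genes, the probe with the highest mean was used, which left 9190 genes. Another probe of a gene is mentioned where its change was opposite to that of the probe used, or for a gene that is followed up. Certain genes of the lists below are not reported here.

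Groups come from the treatment and time labels, and arrays were paired by the donor label, which gives the animal. As a check, arrays of the same animal deviated from their group means together, with correlations from 0.05 to 0.51 (median 0.29), against a median of -0.06 between animals of an arm, and 10 of 11 arrays taken before treatment deviated most like the later array of the same animal. The changes with each antibody and their difference came from 1 limma fit over all arrays with animal as a block, and the comparisons after and before treatment from limma fits over 12 and 11 arrays. Variances were moderated with a trend over intensity, and p-values were adjusted by the Benjamini-Hochberg method with a threshold of 0.05. Log2 changes are after minus before treatment, or anti-IL-15 minus control, and positive values are higher. A probe undetected on all arrays of 1 group is given as a bound against the lowest detected signal. Numbers of sorted cells were compared by exact two-sided permutation tests, and so, after the data were seen, were the BCL2 changes of the arms.

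Before the data were examined, 22 gene lists were fixed, covering cytotoxic effector molecules, natural killer receptors, common gamma chain signalling, STAT5 targets, the cell cycle, naive and central memory genes, effector transcription factors, activation and inhibitory receptors, apoptosis regulators, the type I interferon response, chemokine receptors, glycolysis, oxidative phosphorylation, ribosomal proteins, immediate early genes, T cell receptor and CD8 genes, and markers of 6 other cell types. They were tested with camera at a preset correlation of 0.01 and adjusted over the 22 lists, with an estimated correlation and the fry test as alternatives. Also fixed then were the genes to be named. These were up to 10 of the largest rises and 10 of the largest falls past the threshold that went the same way in every animal, up to 4 members of each list past the threshold or, failing that, 2 with the smallest p, and the set of IL15, IL15RA, IL2RB, IL2RG, BCL2, MKI67, GZMB, PRF1, CD8A, CD8B and CD4. Some were left out for length.

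The fits were tested on simulated data with 200 of 9190 genes changed. For the change with anti-IL-15, 19.4%, 70.1% and 100% of genes changed by 1.5-fold, 2-fold and 4-fold were recovered, and 26.9%, 73.1% and 100% for the control antibody. For the difference between the arms it was 7.46%, 38.8% and 93.9%, for the comparison after treatment 11.9%, 61.2% and 100%, and for that before treatment 10.4%, 59.7% and 100%. Of the unchanged genes 3 to 9 were called. Each gene was drawn independently, so the simulation lacks the correlation between genes of the real arrays, and its error rates may not hold for them.

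Alternatives fixed in advance were a normexp offset of 50, no background correction, 75th percentile scaling, the authors' log2 values, no filter on dim probes, a filter for detection on all arrays at p under 0.01, no block or a random block for the animal, log2 cell number as a covariate, only samples with at least 100000 cells, array weights, the mean of all probes of a gene, every probe on its own, each arm alone, a minimum change of 1.5-fold, and leaving out each animal. The 28S ribosomal RNA probe as a covariate was chosen after seeing the data. A refit on animals chosen by the level of a sex-linked gene was run once and left out, because it picks animals by measured values. The criteria of the test relating the first principal component to cell number and of the test for other cells behind HLA-DRA were tightened after their outcomes were seen, and the test of the 28S probe as a covariate in the control arm was set aside after its outcome was seen, because that level hardly changed on average there.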

Results

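Interleukin-15 (IL-15) is a cytokine that sustains memory CD8+ T cells and natural killer cells, and it signals through a receptor that contains IL2RB and IL2RG. The study treated rhesus macaques with an antibody against IL-15 or with a control antibody of the IgG1 class and followed T cell and natural killer cell homeostasis. CD8+ effector memory T cells (TEM) were sorted from peripheral blood mononuclear cells before and after treatment, and their RNA was measured on Illumina bead arrays. The 23 arrays came from 12 animals. Of the 6 animals given the control antibody all had an array at both times, and of the 6 given anti-IL-15, 5 had both and animal 3 had only the array after treatment. The interval between the times is not given in the sources used here. Each array detected 11263 to 14132 of 47230 probes, 9190 genes were tested, and the number of arrays limits the precision.

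Numbers of sorted cells were compared between the times, and neither arm passed the test. In the anti-IL-15 animals the median was 259000 cells before (n = 5) and 43500 after treatment (n = 6), and all 5 paired animals yielded fewer cells, with a mean log2 ratio of -2.07 ± 0.74 (SD, n = 5), or 4.21-fold lower. The exact two-sided sign-flip permutation p was 0.0625, the smallest that 5 pairs allow. In the control animals the median was 296500 before and 101500 after treatment (n = 6 each), the mean log2 ratio was -1.21 ± 1.52 (SD, n = 6), and the exact permutation p was 0.1875, where 6 pairs allow 0.03125. The number was lower after treatment in 4 control animals and stood at 106% and 173% of its earlier value in control animals 5 and 6. The log2 ratios of the arms differed by -0.86, which was within the spread between animals (exact two-sided permutation p = 0.273).

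The first comparison asked what changed in CD8+ TEM of the same animals after anti-IL-15. BCL2, the founding member of the family of proteins that protect cells from apoptosis, fell in 5 of 5 animals, from a log2 intensity of 7.40 ± 0.17 (SD, n = 5) to 5.10 ± 0.41 (SD, n = 6), and was detected on 3 of the 6 arrays after treatment. Its log2 change was -2.21 (SE 0.22, limma adjusted p = 2.0e-05), or 4.62-fold lower. Another survival gene of this family, BCL2L1, fell by 1.07, and CCND2, a cyclin that drives entry into the cell cycle, fell by 0.99, although another BCL2L1 probe changed by 0.46 in the opposite direction (SE 0.30). The largest rises included IFI27 (2.23, SE 0.25) and ISG15 (1.93, SE 0.25), both induced by interferon, and CDC20 (2.09, SE 0.41), an activator of the anaphase-promoting complex, each in 5 of 5 animals. TYMS, the enzyme that makes thymidylate for DNA synthesis, rose by 1.53, the kinetochore gene CENPW by 1.59, and the histone genes H4C12 and H4C9 were 2.82-fold and 2.67-fold higher. H4C12 also rose with the control antibody, by 0.96, and was called there. Without a call, ISG15 averaged 8.58 before and 9.41 after the control antibody, and CDC20 5.64 and 6.60.

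In all, 75 of 9190 genes passed a limma adjusted p under 0.05 after anti-IL-15, of which 41 rose and 34 fell, and 39 and 33 of these moved the same way in every paired animal. Among the called genes that rose in every paired animal, the other large rises were MYL6B (1.66), the respiratory complex I subunit NDUFB7 (1.58) and TRIB1 (1.41). Besides BCL2, the largest falls among those lower in every paired animal were AFAP1L2 (-2.18), the small GTPase RAB27B (-1.93), the tubulin TUBB2B (-1.92), CPNE8 (-1.85), IGIP (-1.63), VPS37C (-1.57), ZNF219 (-1.51), NUDT11 (-1.41) and LFNG (2.82-fold lower). CPNE8 changed by only -0.07 and -0.16 in animals 2 and 5. It was detected on 3 of 5 arrays before and 1 of 6 after treatment, so its size rests on the other animals. The chemokine receptor CX3CR1, carried by cytotoxic effector cells, fell by 1.26 (adjusted p = 0.0391), the transcription factor RUNX3 fell by 0.94 and the activating receptor NCR3 fell by 0.99, the last in 4 of 5 animals. For RUNX3 another probe changed by 0.23 (SE 0.26), in the opposite direction. The glucose transporter SLC2A3 rose by 0.97 and the MHC class II gene HLA-DRA rose by 1.13. The count was 5 without anti-IL-15 animal 1, 11 without animal 2 and 164 without animal 6, 20 with the 28S ribosomal RNA probe as a covariate, and 2 with log2 cell number as a covariate, where BCL2 kept its call. It was 1 with no replicate block, where BCL2 was the gene called.

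Genes of the IL-15 receptor and of cytotoxic function did not pass the test in this arm. IL2RB had a change of -0.73 (SE 0.23, adjusted p = 0.142, lower in 5 of 5 animals), IL2RG of -0.37 (adjusted p = 0.576), and IL15 itself of 0.41 (adjusted p = 0.335). PRF1, which encodes the pore-forming protein perforin, had a change of -1.08 (SE 0.32, adjusted p = 0.113), GZMB, a granzyme, of -0.00 (SE 0.26, adjusted p = 0.995), CD8A of -0.40 (adjusted p = 0.208) and CD8B of -0.04 (adjusted p = 0.947). Other CD8A probes changed by 0.31 (SE 0.23), in the opposite direction, and by -0.35 (SE 0.16). Another CD8B probe changed by 0.22 (SE 0.18), also in the opposite direction. IL15RA, MKI67 and CD4 were not among the genes tested.

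Of the 22 gene lists, 4 moved upward after anti-IL-15 by camera with a preset correlation. In the cell cycle list 21 of 24 measured genes had changes above 0, with a median of 0.45 (adjusted p = 1.4e-09, and adjusted p = 0.135 with an estimated correlation). CDC20, TYMS and the cyclins CCNA2 (0.92) and CCNB2 (0.89) passed over all genes tested, and 10 genes rose when adjusted over the list alone. In the list of type I interferon response genes 11 of 13 had changes above 0, with a median of 0.24 (adjusted p = 7.5e-05, and adjusted p = 0.0312 with an estimated correlation). IFI27 and ISG15 passed, and 3 rose when adjusted over the list alone. In the list of activation and inhibitory receptors 9 of 10 were above 0, with a median of 0.50 (adjusted p = 2.9e-04, and adjusted p = 0.0928 with an estimated correlation). Only HLA-DRA passed over all genes, and 2 rose when adjusted over the list alone. In the oxidative phosphorylation list 21 of 25 were above 0, with a median of 0.36 (adjusted p = 6.0e-08, and adjusted p = 0.197 with an estimated correlation), and none passed over all genes while 2 did when adjusted over the list alone. COX6A1 had a change of 0.98 (adjusted p = 0.113) and UQCRH of 0.83 (adjusted p = 0.105).

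**Figure D1:**
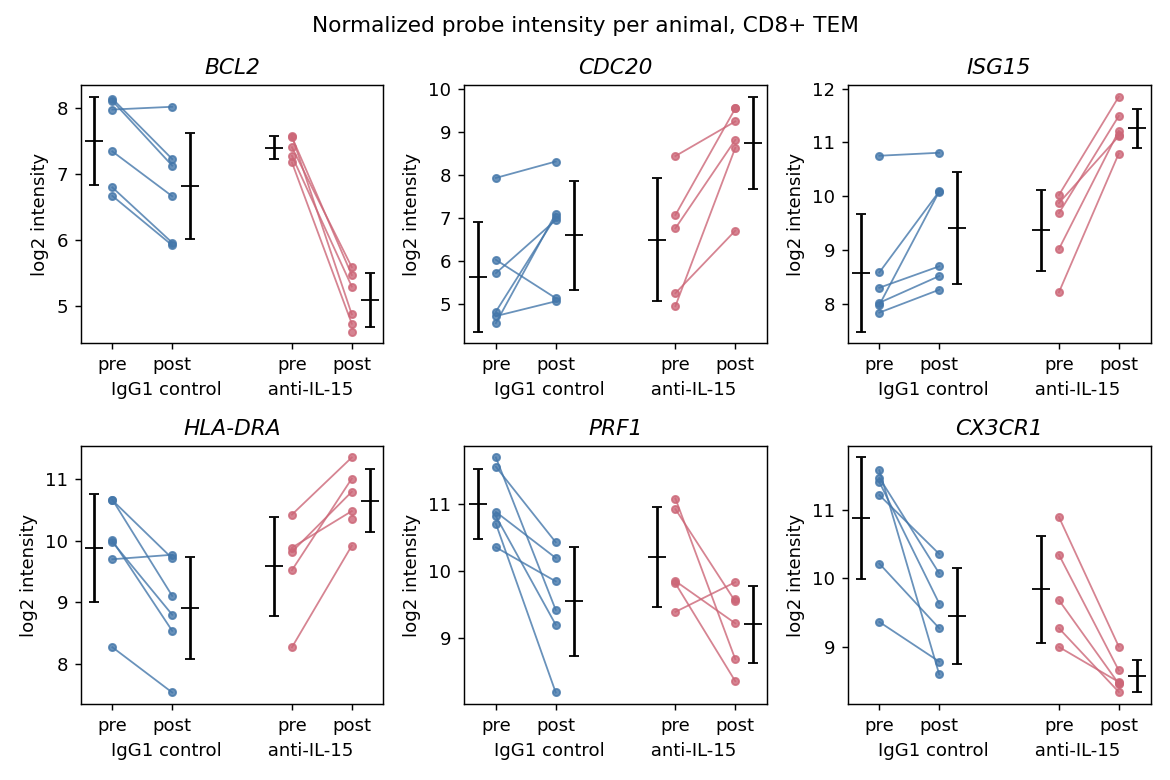
Normalised log2 intensity of 6 genes in each animal before (pre) and after (post) treatment, with IgG1 control animals in blue and anti-IL-15 animals in red. Lines join the arrays of 1 animal, the animal without a line has only the array after treatment, and bars give the mean ± SD of each group. BCL2 fell in all 5 paired anti-IL-15 animals to 5.10 ± 0.41 (SD, n = 6), and HLA-DRA rose in these 5 and fell in 5 of 6 control animals.

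The second comparison asked what changed over the same period with the control antibody. IER2, an immediate early gene, rose from 6.11 ± 1.33 to 8.24 ± 0.52 (SD, n = 6), a log2 change of 2.13 (SE 0.33, limma adjusted p = 0.0102) in 6 of 6 animals. PRF1 fell by 1.46 (SE 0.29, adjusted p = 0.0185) and CX3CR1 fell by 1.43 (SE 0.25, adjusted p = 0.0102), each in 6 of 6 animals. NKG7, a cytotoxic granule protein, fell by 0.97, CD8A fell by 0.77, the adhesion molecule CD2 fell by 0.81 and HLA-DRA fell by 0.97, the last in 5 of 6 animals. The chemokine CCL5 fell by 1.09 on its brightest probe, while another CCL5 probe changed by 0.54 (SE 0.19) in the opposite direction. Of the other CD8A probes, 1 had a change of 0.01 and 1 of -0.63.

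In the control arm 201 of 9190 genes passed, 66 higher and 135 lower, and 58 and 99 of these moved the same way in every animal. Of the called genes higher in every animal, the largest rises after IER2 were the Cajal body RNA SCARNA9L (2.08), ZNF563 (1.31), CHST2 (1.29), MRPS21 (1.24), ATP2A3 (1.11), the transcription factor ZNF683 (1.09), ARMC5 (1.09), the non-coding RNA SNHG6 (1.07) and MCM3AP (1.05). Another probe of ATP2A3 changed by -0.38 (SE 0.17). Of the called genes lower in every animal, the largest falls were LOC644936 (-1.76), PRF1, CX3CR1, CFAP210, ENPP4 (-1.27), TRIM22 (-1.24), RBL2 (-1.24), RAB11FIP1 (-1.18), ZFC3H1 (-1.15) and DRD3 (-1.13). The greatest change of any called gene was 5.22-fold, in a gene that did not move the same way in every animal. CFAP210 was detected on 4 of 6 arrays before and on 0 after treatment, and was at least 2.00-fold lower (adjusted p = 0.0104). Other probes of RAB11FIP1 and DRD3 changed by 0.21 and 0.04. TNFRSF18, a costimulatory receptor, fell by 1.08, in 4 of 6 animals. BCL2 had a change of -0.69 (SE 0.20, adjusted p = 0.0614), IL2RB of -0.71 (adjusted p = 0.0695), IL2RG of -0.60 (adjusted p = 0.227), GZMB of -0.23 (adjusted p = 0.656), CD8B of -0.40 (adjusted p = 0.254) and IL15 of -0.14 (adjusted p = 0.737). Other BCL2 probes changed by 0.16, -0.31 and 0.22. The count was 0 without control animal 1, 16 without animal 2, 30 without animal 4 and 367 without animal 3, and 23 with no replicate block. It was 0 with log2 cell number as a covariate, 875 with the 28S ribosomal RNA probe as a covariate, and with 75th percentile scaling 350, of which 71 were higher and 279 lower. The excess of lower genes shrank with detection on all arrays required (130 higher and 136 lower) and without anti-IL-15 animal 6 (128 and 172).

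In the control arm 2 lists moved downward. All 14 measured genes of the list of cytotoxic effector molecules had changes below 0, with a median of -0.27 (camera adjusted p = 7.1e-04, and adjusted p = 0.243 with an estimated correlation). PRF1, CCL5 and NKG7 passed over all genes, and 4 fell when adjusted over the list alone. In the list of T cell receptor and CD8 genes the median of 10 genes was -0.31 (adjusted p = 0.0162, and adjusted p = 0.538 with an estimated correlation), and CD2 and CD8A passed over all genes and when adjusted over the list alone. Members of lists that were not called also passed. The ribosomal protein genes RPS28, RPL35 and RPS13 rose by 1.04, 1.02 and 0.85, while the median of 29 such genes was 0.05. The respiratory chain genes UQCRH and NDUFA1 rose by 0.94 and 0.68 and ATP5F1A fell by 0.57, and another UQCRH probe changed by -0.16.

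Technical measures also varied between the arrays. The probe for 28S ribosomal RNA had log2 changes of 3.66 to 4.28 in 5 animals, control animals 1 and 4 and anti-IL-15 animals 1, 2 and 5, and of -3.62 to 0.13 in the other 6. Its level averaged 8.59 ± 1.95 before and 8.73 ± 2.13 after treatment (SD, n = 6 each) in the control arm, and 8.19 ± 1.54 (SD, n = 5) and 9.74 ± 1.77 (SD, n = 6) with anti-IL-15. The first principal component averaged -20.4 ± 17.9 before and 3.76 ± 17.9 after treatment (SD, n = 6 each) in the control arm, and -3.01 ± 13.8 (SD, n = 5) and 19.1 ± 6.73 (SD, n = 6) with anti-IL-15. It changed by 28.03 to 54.9 in the 5 animals with the larger 28S changes and by -1.96 to 30.8 in the other 6, and no correlation is given because the 28S changes lie in separate clusters. Across the 11 paired animals its change had a Pearson r of -0.717 with the log2 ratio of cell numbers (permutation p = 0.0140, adjusted 0.0517 over 4 relations computed) and a Spearman rho of -0.709 (permutation p = 0.0181). Leaving out the 2 animals farthest from the median cell ratio gave r = -0.684. Within the control arm r was -0.897 (n = 6, exact permutation p = 0.0417, adjusted 0.0556) and rho was -0.771 (exact permutation p = 0.103), with r = -0.966 without the 2 farthest animals, and no correlation was computed over the 5 pairs of the anti-IL-15 arm. There the component changed by 38.2, 28.03 and 12.9 in the animals with log2 cell ratios of -2.71, -2.65 and -2.49, and by 4.26 and 36.3 in those with -1.28 and -1.25.

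**Figure D2:**
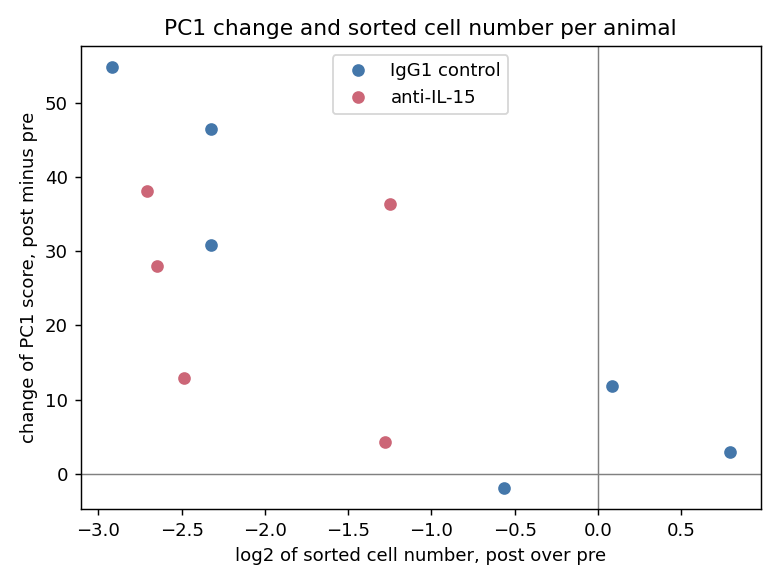
Change of the first principal component score, after minus before treatment, on the vertical axis against the log2 ratio of sorted cell numbers, after over before, on the horizontal axis. Each of the 11 points is 1 paired animal, with 6 control animals in blue and 5 anti-IL-15 animals in red. The 3 control animals with the largest loss of cells have changes of 30.8 to 54.9 and the other 3 of -1.96 to 11.8.

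No list of markers of another cell type was called in any comparison. After anti-IL-15 the medians were -0.01 for B cells (4 genes), 0.06 for monocytes and dendritic cells (8), 0.01 for neutrophils (3), -0.12 for platelets and erythrocytes (6), 0.11 for CD4 and regulatory T cells (4) and 0.08 for gamma delta and MAIT T cells (4). With the control antibody the same medians were 0.09, 0.09, 0.01, 0.19, -0.10 and 0.17. The full lists held 13, 17, 10, 13, 11 and 11 genes, so many markers were not measured. Some measured ones averaged near the lowest detected signal of 4.90, such as MS4A1 at 4.91 and LYZ at 4.87. Small medians therefore say little about other cells in the sort. Among single markers, the B cell receptor component CD79B had a change of 1.25 with the control antibody (adjusted p = 0.0659), the erythrocyte gene HBB of 0.85 with the control antibody (adjusted p = 0.0713) and of -0.73 with anti-IL-15 (adjusted p = 0.211), and CD14, a monocyte marker, of -0.52 with anti-IL-15 (adjusted p = 0.280).

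The remaining lists were not called after either antibody. Medians after anti-IL-15 and with the control antibody were -0.06 and -0.09 for natural killer cell receptors, -0.13 and -0.21 for common gamma chain cytokine signalling, 0.06 and 0.11 for STAT5 target genes, 0.08 and -0.24 for effector T cell transcription factors, -0.11 and 0.08 for apoptosis regulators, and -0.05 and -0.19 for chemokine receptors. They were -0.37 and 0.06 for naive and central memory genes, 0.05 and -0.14 for glycolysis, 0.02 and 0.05 for ribosomal proteins, and 0.24 and 0.22 for immediate early and stress genes. For the STAT5 targets and effector transcription factors after anti-IL-15, and for the STAT5 targets and apoptosis regulators with the control antibody, mean and median had opposite signs, with means of -0.13, -0.07, -0.03 and -0.13. The same held for neutrophil markers in both arms (means of -0.05 and -0.17) and, with the control antibody, for activation receptors (-0.15) and the type I interferon response (0.02). For the chemokine receptors after anti-IL-15 the direction of the camera test was opposite to that of the median. Lists called in 1 arm had medians in the other of 0.00 (cell cycle), -0.06 (type I interferon response), 0.05 (activation receptors) and 0.01 (oxidative phosphorylation) with the control antibody, and of -0.00 (cytotoxic molecules) and -0.20 (T cell receptor and CD8) with anti-IL-15.

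**Figure D3:**
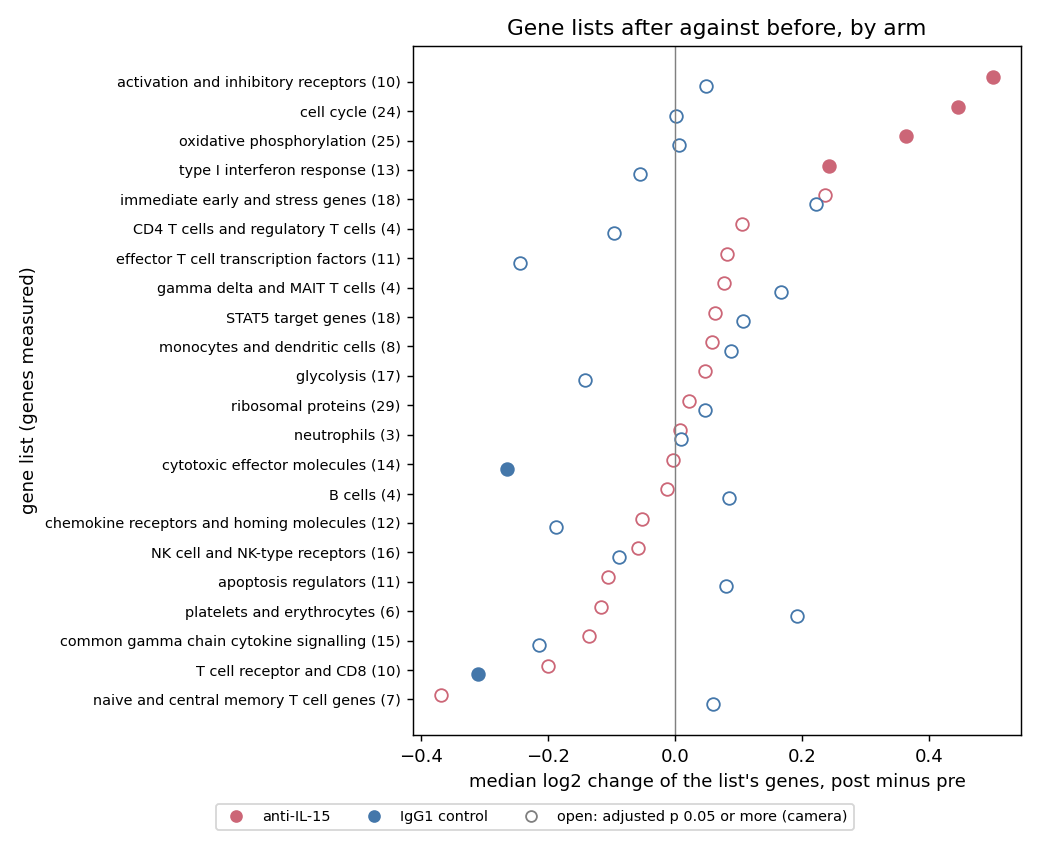
Median log2 change after against before treatment over the measured genes of each of the 22 lists, whose number stands in brackets, for the anti-IL-15 arm in red and the control arm in blue. Filled points have a camera adjusted p under 0.05 with a preset correlation. The 4 filled red points lie between 0.24 and 0.50 and the 2 filled blue points at -0.27 and -0.31.

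The third comparison set the change with anti-IL-15 against the change with the control antibody. HLA-DRA, which encodes the alpha chain of the MHC class II molecule HLA-DR, was the gene called, with an interaction of 2.10 (SE 0.29, limma adjusted p = 0.00614). It rose in 5 of 5 anti-IL-15 animals and fell in 5 of 6 control animals, and another HLA-DRA probe had an interaction of 1.10 (SE 0.27). BCL2 had an interaction of -1.52 (SE 0.29, adjusted p = 0.105) and IFI27 of 1.72 (SE 0.34, adjusted p = 0.105), so for neither did the difference between the arms pass over all genes. Adjusted over the list alone, p was 4.7e-04 for BCL2 among the apoptosis regulators and 6.5e-04 for IFI27 in the type I interferon response. The BCL2 changes of the animals were -2.70 to -1.82 with anti-IL-15 (n = 5) and -0.98 to 0.04 with the control antibody (n = 6), with an exact two-sided permutation p of 0.00216, the smallest that 11 animals allow. The interaction was 0.37 for PRF1 (adjusted p = 0.831), -0.02 for IL2RB (0.987), 0.22 for IL2RG (0.906), 0.22 for GZMB (0.889), 0.55 for IL15 (0.529), 0.37 for CD8A (0.580) and 0.36 for CD8B (0.721), the values in brackets being adjusted p of limma. In all 891 genes had an unadjusted p under 0.05. Without anti-IL-15 animal 2 the HLA-DRA interaction was 1.97 (adjusted p = 0.0509), and no gene was called with no replicate block (HLA-DRA 2.04, adjusted p = 0.636) or a random one (2.05, adjusted p = 0.338). Among the 4 control and 2 anti-IL-15 animals with at least 100000 cells at both times it was 2.11 (SE 0.41, adjusted p = 0.217). With the 28S ribosomal RNA probe as a covariate 30 genes were called, 22 higher and 8 lower.

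By camera 5 lists moved upward with anti-IL-15 relative to the control antibody, and none held with an estimated correlation. The medians were 0.59 for the cell cycle (adjusted p = 3.9e-07, and adjusted p = 0.180 with an estimated correlation), 0.44 for the type I interferon response (9.1e-04, and adjusted p = 0.0641 with an estimated correlation) and 0.33 for cytotoxic effector molecules (0.00122, and adjusted p = 0.155 with an estimated correlation). This last list had a median difference between the arms of -0.32 before treatment (adjusted p = 0.00811, and adjusted p = 0.745 with an estimated correlation) and of -0.05 after it (adjusted p = 0.959), and its median change was -0.27 with the control antibody and -0.00 with anti-IL-15. They were 0.31 for activation and inhibitory receptors (9.8e-04, and adjusted p = 0.138 with an estimated correlation) and 0.20 for oxidative phosphorylation (9.8e-04, and adjusted p = 0.402 with an estimated correlation). HLA-DRA was the only member of these lists to pass over all genes. Adjusted over the list alone, 5 cell cycle genes, 2 interferon response genes, 2 activation receptors, 1 cytotoxic gene and 0 oxidative phosphorylation genes passed, all higher. TYMS had an interaction of 1.27, the replication gene MCM5 of 1.14, ISG15 of 1.10, CCL5 of 1.11 and NKG7 of 0.97, and none of these passed over all genes. Another CCL5 probe had an interaction of -0.39 (SE 0.29), in the opposite direction.

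The called genes of the arms were compared. Of 41 and 66 genes called higher, 3 were in both sets, where independent sets would share 0.294, and of 34 and 135 called lower, 3 were shared, where independent sets would share 0.499. H4C12 was among the shared rises and CX3CR1 among the shared falls. HLA-DRA was the 1 gene called in both arms in opposite directions. The arms hold different animals. The changes of the arms had a Pearson r of 0.381 across all tested genes, which are not independent replicates. Of the 75 genes called with anti-IL-15, 62 had a change in the same direction in the control arm, and of the 201 called with the control antibody, 161 did so with anti-IL-15.

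The fourth comparison set the 6 anti-IL-15 animals against the 6 control animals after treatment. NCR3, which encodes the activating natural killer receptor NKp30, was 3.25-fold lower with anti-IL-15, at 8.98 ± 0.41 against 10.7 ± 0.50 (SD, n = 6 each), a log2 difference of -1.70 (SE 0.24, limma adjusted p = 0.0131). It was the gene called, while 732 had an unadjusted p under 0.05. Before treatment NCR3 averaged 10.0 ± 1.02 (SD, n = 5) in the anti-IL-15 arm and 10.6 ± 0.71 (SD, n = 6) in the control arm. Its interaction was not called, so part of the gap may predate the antibody. IFI27 differed by 2.77 (SE 0.49), HLA-DRA by 1.74 (SE 0.33) and BCL2 by -1.73 (SE 0.33), each with an adjusted p of 0.0750, and ISG15 by 1.86 (adjusted p = 0.0800). Before treatment the anti-IL-15 and control means were 7.83 and 6.90 for IFI27 and 9.36 and 8.58 for ISG15. They were 9.58 and 9.88 for HLA-DRA and 7.40 and 7.51 for BCL2. IL2RB differed by -0.25, IL2RG by -0.50, IL15 by 0.29, PRF1 by -0.34, GZMB by -0.12, CD8A by -0.07 and CD8B by 0.28, and none of these passed. Other CD8A probes differed by 0.23 (SE 0.25), in the opposite direction, and by -0.11 (SE 0.16). The NCR3 call was lost without control animal 5 or 6 and without anti-IL-15 animal 3 or 6 (adjusted p = 0.0631, 0.0563, 0.0578 and 0.0519), and 19 genes were called without anti-IL-15 animal 5. It was also lost with only the 2 anti-IL-15 and 4 control arrays of at least 100000 cells (-1.81, adjusted p = 0.373). The count was 18 with a random replicate block, 11 with log2 cell number as a covariate and 11 with array weights.

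After treatment 5 lists were higher with anti-IL-15 by camera. The cell cycle list had 22 of 24 genes above 0 and a median of 0.90 (adjusted p = 1.1e-20, and adjusted p = 0.0652 with an estimated correlation), with 0 genes past the threshold over all genes and 16 when adjusted over the list alone. TYMS differed by 1.94 and CCNB2 by 1.23. All 25 oxidative phosphorylation genes were above 0, with a median of 0.35 (adjusted p = 3.4e-10, and adjusted p = 0.0468 with an estimated correlation), and 3 passed when adjusted over the list alone. The median was 0.16 for the type I interferon response (adjusted p = 1.1e-04, and adjusted p = 0.0990 with an estimated correlation) and 0.56 for activation and inhibitory receptors (adjusted p = 6.7e-04, and adjusted p = 0.0652 with an estimated correlation). It was 0.18 for glycolysis (adjusted p = 0.0249, and adjusted p = 0.0759 with an estimated correlation). Adjusted over the list alone 3, 3 and 0 genes of these lists passed, and over all genes 0 did.

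Before treatment the arms were compared as a baseline. Limma called 0 of 9190 genes, with a smallest adjusted p of 0.325 and 964 genes at an unadjusted p under 0.05. Already at this time the list of cytotoxic effector molecules was lower in the animals assigned to anti-IL-15, with a median of -0.32, and the cell cycle list was higher, with a median of 0.25 (camera adjusted p = 0.00811 for both). With an estimated correlation the adjusted p was 0.745 for the cytotoxic list and 0.835 for the cell cycle list.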

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

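The tests of the 28S covariate, the other BCL2 probes, the arms permuted over the BCL2 changes and the markers of other cells, and the shares a change had to keep with cell number as a covariate, were chosen only after results were seen. The test of held-out animals was chosen after the data were seen but before its own result. The criterion for markers of other cells was tightened after its outcome was seen.

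HLA-DRA changed differently in the arms by the interaction test (2.10, SE 0.29, limma adjusted p = 0.00614), rising in 5 of 5 anti-IL-15 animals and falling in 5 of 6 control animals. Few sorted cells as the whole cause is argued against by animals with similar losses. Control animals 1, 2 and 4, with log2 cell ratios of -2.32, -2.32 and -2.92, had HLA-DRA changes of -1.18, -1.56 and -0.74. Anti-IL-15 animals 1, 2 and 4, with ratios of -2.71, -2.65 and -2.49, had changes of 0.93, 1.65 and 0.59. With log2 cell number as a covariate the interaction kept 1.05 of its size (2.21, limma adjusted p = 0.00313). The mean log2 ratios of the arms differed by -0.86, so a shared slope could shift it only in part, and this adds little. Among the 4 control and 2 anti-IL-15 animals with at least 100000 cells at both times the interaction was 2.11. The call was lost there (limma adjusted p = 0.217), with fewer arrays and an SE of 0.41 against 0.29. B cells or monocytes, which carry class II genes abundantly and which the sort would remove, may still contribute. The median interaction of the B cell markers was -0.134 and that of the monocyte and dendritic cell markers -0.148, which would speak against them, but 0 of 4 and 1 of 8 markers were detected on all arrays, clear of the floor and no brighter than HLA-DRA, so the test decides nothing. The antibody itself, the biological explanation that the design gives, stays open and is the contrast tested here.

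BCL2 fell by 2.21 on the log2 scale with anti-IL-15, in 5 of 5 animals. With log2 cell number as a covariate 0.940 of this was kept (-2.08, SE 0.34, limma adjusted p = 0.0270). Every paired anti-IL-15 animal yielded fewer cells, so that value is extrapolated along a slope shared by both arms. Control animals 1, 2 and 4 had log2 cell ratios of -2.32, -2.32 and -2.92 and BCL2 changes of -0.75, -0.68 and -0.98. Those falls were smaller than any with anti-IL-15 (-2.70 to -1.82), which argues against cell number as the whole cause. The 3 other BCL2 probes changed by -0.36, -0.48 and -1.44 with anti-IL-15, all below 0, with a mean of -0.758 (SE 0.189). That argues against a misreading probe for the direction of the change, while its size rests on the probe used. The size also depended on the background correction, at -1.50 with an offset of 50 and -1.09 with no correction. With the control antibody these probes changed by 0.16, -0.31 and 0.22. Their interactions, in the same order, were -0.52 (SE 0.29), -0.17 (SE 0.24) and -1.65 (SE 0.37). On the probe used, a change with time shared by both arms is argued against as the whole cause. There the control arm changed by -0.69 and the interaction was -1.52 (95% interval -2.13 to -0.91, limma adjusted p = 4.7e-04 over the list of apoptosis regulators alone, exact permutation p = 0.00216). Over all genes that interaction had an adjusted p of 0.105, so the antibody stays a hypothesis, by which loss of IL-15 signalling may lower BCL2 beyond the change seen with the control antibody.

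The 201 genes called with the control antibody were those of a treatment that does not target IL-15. The first principal component averaged -20.4 in the control arm before treatment, 3.76 after it, and -3.01 in the anti-IL-15 arm before treatment. For each of this arm's largest rises and falls named above, the anti-IL-15 mean before treatment lay between the control means before and after. These genes were picked for a large change in this arm, which by itself favours such a place, so this decides nothing. Limma called 0 genes between the arms before treatment, and a change with time cannot be told apart from where the control arm started. The 28S level averaged 8.59 before and 8.73 after treatment in this arm, so a straight-line trend with it could shift the mean changes little. That also fixed the share of the median change kept with it as a covariate near 1 (0.981), so that test decides nothing more. All 201 genes kept their call and sign there, and RNA quality that the 28S level does not follow stays open. With anti-IL-15, where the level averaged 8.19 before and 9.74 after, the 75 genes kept 0.872 of their median size (0.95 against 1.09) and all 75 their sign, with 20 still past the threshold. The number of sorted cells may contribute too and cannot be told apart from time. In each animal, over the 200 genes with the strongest evidence in the others, the mean signed change was 0.33 in the 2 animals whose cell number did not fall and 0.68 in the 4 whose number fell, a ratio of 0.492, with r = -0.785 (n = 6, exact permutation p = 0.0889). Spearman rho was -0.543 (exact permutation p = 0.297). Control animal 3, whose number fell to 68% of its earlier value, had the lowest value, 0.18. Control animals 5 and 6, whose number did not fall, had 0.31 and 0.36. With cell number as a covariate 0 genes were called, their median size went from 0.84 to 0.60 while the median SE rose from 0.19 to 0.23, and all 201 kept their sign.

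Other splits of the same animals into times or arms were counted for each comparison. For the control antibody 1 of 32 splits gave as many as 201 genes, the real one, and the highest of the others gave 14. This is the smallest share that 32 splits allow, and it was not adjusted over the comparisons. It argues against chance without excluding it. For anti-IL-15, 16 splits are too few to tell, with 75 genes in the real one and 8 in the highest other. For its 4 lists 6 of 16 splits gave as many and the highest other gave 7, so chance cannot be excluded, and 16 splits could not have excluded it either way. Chance cannot be excluded for the 2 lists of the control antibody (15 of 32 splits, highest other 3), the 1 gene and 5 lists that differed between the arms (11 and 15 of 100 splits, highest others 448 and 8), the 1 gene and 5 lists after treatment (8 and 9 of 100, highest others 3 and 7) and the 2 lists before it (49 of 100, highest other 6). For the 0 genes before treatment the count decides nothing, since any split gives at least 0, and the highest other gave 102. That split set control animals 1, 2, 4, 5 and 6 against the rest, which is the real one with control animal 3 moved to the anti-IL-15 side. The split with 448 genes set control animals 1 and 4 and anti-IL-15 animals 1, 2 and 5 against the other 6, which are the 5 animals whose 28S probe rose by 3.66 to 4.28, and so points to a structure of the samples apart from treatment. With the 28S probe as a covariate 30 genes differed between the arms.

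Lists of genes, 5 in number, also differed between the arms by the camera test of the interaction. Adjusted p were 0.00122 for cytotoxic effector molecules, 3.9e-07 for the cell cycle, 9.8e-04 for activation and inhibitory receptors, 9.1e-04 for the type I interferon response and 9.8e-04 for oxidative phosphorylation, and with an estimated correlation 0 lists were called.

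Single animals stood far from the rest of their group for 7 of 120 groups of values tested, where chance gives about 1 in 20. TRIB1 changed by 2.06 in anti-IL-15 animal 1 and IGIP by -0.19 in animal 6. SNHG6 changed by 2.25 in control animal 2, TNFRSF4 by 0.95 in control animal 4 and BCL2 by 0.042 in control animal 5. Control animal 3 had a first principal component of 15.2 before treatment, and anti-IL-15 animal 5 a second component of -45.9 after treatment.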

How the results depend on the processing

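The 28S covariate was chosen after seeing the data and the other settings before. Counts of genes are in the order anti-IL-15, control antibody, difference between the arms and after treatment, where the reported counts were 75, 201, 1 and 1. On the probe used, or the mean of its probes where that was the setting, none of the 75, 201, 1 and 1 called genes changed direction under any setting that tested it. BCL2 after anti-IL-15 stayed past the threshold under every setting that tested it, with changes from -2.31 to -1.09 and an adjusted p of at most 0.0471. It was filtered out, and so not tested, where detection on all arrays was required. For the changes of count and sign below the cause was not tested, apart from settings that use fewer samples or test other numbers of genes. A block for the slide was not run, since the sources used here do not name it. Of the 136 gene results 130 held their side under the authors' values and 67 with the cell number covariate. Signals near the floor limit dim genes.

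After treatment 3 genes were called with an offset of 50, and 2 for the difference and 3 after treatment with no background correction and with the authors' log2 values alike. With 75th percentile scaling 350 genes (71 higher, 279 lower) were called for the control antibody and 8 lists for the difference, the IL2RB difference was 0.0112 and CD8A after treatment 1.38e-04. No filter on dim probes gave 27 and 71 genes over 20044 tested. Detection on all arrays gave 31 genes for anti-IL-15 and 3 after treatment over 4351 tested, and 1 list for the control antibody. Array weights gave 167, 2 for the difference and 11 after treatment, with GZMB at 0.0855 after anti-IL-15 and 0.0315 after treatment, IL2RG at -0.12 for the difference and CD8A at 0.0202 after treatment. The mean of all probes gave CD8B 0.0904 after anti-IL-15 and CD8A 0.0195 after treatment, every probe on its own 48 calls for anti-IL-15, and each arm alone 24 genes for the control antibody. The minimum of 1.5-fold gave 74, 181, 1 and 1.

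The replicate block was part of the reported fits. With no replicate block the counts were 1, 23 and 0, and CD8B after anti-IL-15 was 0.0250. With a random replicate block they were 15 for anti-IL-15, 0 for the difference and 18 after treatment, and CD8B was 0.0160. The paired fit changed no other count of calls by over 1.5 times.

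With log2 cell number as a covariate the counts were 2, 0, 2 and 11, and 2 lists were called for anti-IL-15. COX6A1 was -0.0198 and IL2RG 0.70 after anti-IL-15, IL15 0.14 and IL2RG 0.0307 with the control antibody, IL2RB 0.24 for the difference, and IL2RB 0.12, PRF1 0.0651 and CD8A 0.12 after treatment. Samples with at least 100000 cells, 2 pairs with anti-IL-15 and 4 with the control antibody, gave 3, 0, 1 and 0. The 1 was FGF9, chosen after its value was seen (-2.92, adjusted p = 0.0315), and HLA-DRA lost its call at 2.11 (adjusted p = 0.217). There MAF was -0.54 and CD8B 0.14 after anti-IL-15, CD79A 0.0173 and IL15 0.14 with the control antibody, IL2RB 0.16, IL2RG -0.0756 and GZMB -0.19 for the difference, and GZMB 0.26 after treatment. The 28S covariate gave 20, 875, 30 and 6, where the 75 genes kept 0.872 of their median size and all 75 their sign, with IL2RG 0.0737 after anti-IL-15, IL2RB 0.22 and GZMB -0.0326 for the difference, and CD8A 0.0420 after treatment. Camera with an estimated correlation called 1, 0, 0 and 1 lists, and fry 1 for the control antibody and 2 for the difference.

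Leaving out 1 animal at a time, counts ranged from 5 to 164 for anti-IL-15, 0 to 367 for the control antibody, 0 to 2 for the difference, 0 to 19 after and 0 to 1 before treatment. For anti-IL-15 they were 5, 11, 21, 42 and 164 without anti-IL-15 animals 1, 2, 4, 5 and 6, and 128, 29 and 39 without control animals 4, 5 and 6. For the control antibody they were 0, 16, 367 and 30 without control animals 1, 2, 3 and 4, and 116 without anti-IL-15 animal 2. The difference had 0 without anti-IL-15 animal 2 and 2 without control animal 4. After treatment 0 were called without control animals 5 or 6 or anti-IL-15 animals 3 or 6, 7 without control animal 3 and 19 without anti-IL-15 animal 5, and before treatment 1 without control animal 3 or 5. Lists ranged from 2 to 4 for the control antibody (4 without control animal 2) and 4 to 8 for the difference (8 without anti-IL-15 animal 2). After anti-IL-15, CD22 ranged from -0.23 to 0.11, MGAM from -0.0708 to 0.15, GZMB from -0.13 to 0.23 and CD8B from -0.15 to 0.16. With the control antibody, CD79A ranged from -0.33 to 0.00603, MGAM from -0.00665 to 0.15 and IL15 from -0.32 to 0.0353. The difference ranged from -0.15 to 0.13 for IL2RB and -0.00999 to 0.70 for PRF1, and after treatment GZMB ranged from -0.33 to 0.21 and CD8A from -0.16 to 0.0504.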

Other observations

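The gene groups other than the cell cycle list, their tests, and the weighing of cell number for the cell cycle list and the first principal component were chosen after values had been seen. The cell cycle list and the cell number covariate were not.

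Histone genes rose as a group after anti-IL-15. Of 24 measured, 23 had changes above 0, with a median log2 change of 0.62, 5 passed over all genes, and camera gave an adjusted p of 5.4e-17 (adjusted p = 0.0136 with an estimated correlation). With the control antibody 21 of 24 were above 0 with a median of 0.36 (adjusted p = 6.2e-06, and adjusted p = 0.193 with an estimated correlation), and the difference between the arms had a median of 0.32 (adjusted p = 5.4e-04, and adjusted p = 0.228 with an estimated correlation). Guanylate binding protein and immunoproteasome genes, which interferon gamma induces, had a median of 0.44 over 9 genes after anti-IL-15 (adjusted p = 1.6e-06, and adjusted p = 0.0136 with an estimated correlation). With the control antibody it was 0.10 (adjusted p = 0.315), and the difference had a median of 0.30 (adjusted p = 5.6e-04, and adjusted p = 0.0537 with an estimated correlation).

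The class II genes were grouped after HLA-DRA was seen, and it is among them, so the group partly restates its change. After anti-IL-15, 2 of 14 passed, both higher, and 12 had changes above 0, with a median of 0.50 (adjusted p = 3.4e-08, and adjusted p = 0.0181 with an estimated correlation). With the control antibody 1 of 14 passed, lower, and 1 was above 0, with a median of -0.25 (adjusted p = 0.00649, and adjusted p = 0.193 with an estimated correlation). For the difference 1 of 14 passed, and all 14 were above 0, with a median of 0.77 (adjusted p = 5.6e-12, and adjusted p = 0.0157 with an estimated correlation). Without HLA-DRA the medians of the other 13 were 0.47, -0.23 and 0.58, with adjusted p of 8.9e-07, 0.0331 and 1.5e-09, and adjusted p of 0.0248, 0.276 and 0.0247 with an estimated correlation. Small nucleolar and Cajal body RNAs had medians of 0.01 and 0.03 over 96 genes after anti-IL-15 and the control antibody (adjusted p = 0.116 and 0.0335, and adjusted p = 0.232 and 0.193 with an estimated correlation), and of 0.00 for the difference (adjusted p = 0.595).

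A hypothesis was that fewer sorted cells account for the rise of the cell cycle list after anti-IL-15. With log2 cell number as a covariate the median change kept 0.955 of its value (0.43 against 0.45). The list kept its call with a preset correlation (camera adjusted p = 5.1e-05). That cannot settle the hypothesis, since every paired anti-IL-15 animal yielded fewer cells and the value is extrapolated along a slope both arms share. With an estimated correlation the list was not called without the covariate (adjusted p = 0.135) or with it (adjusted p = 0.367). An effect of the antibody on proliferation may remain, as a hypothesis only, since the difference between the arms had an adjusted p of 0.180 with an estimated correlation and the list was already higher before treatment with a preset correlation (adjusted p = 0.00811, and adjusted p = 0.835 with an estimated correlation).

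Another hypothesis was that the first principal component follows the number of sorted cells. Across 11 animals r was -0.717 (permutation p = 0.0140), which passes unadjusted and not when adjusted over the 4 relations computed (0.0517). The adjusted value was taken as the criterion after both had been seen. The 28S level, taken here as a possible sign of RNA quality that was not checked, also varied. The component changed by 28.03 to 54.9 in the 5 animals whose 28S probe rose by 3.66 to 4.28 and by -1.96 to 30.8 in the other 6. Those 5 animals had log2 cell ratios of -2.92 to -1.25, and the other 6 of -2.49 to 0.79, so the 2 measures are entangled. Cell number and RNA quality may each be part of what moves the arrays with time, but these data cannot separate them, and both stay open.

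Among 4613 probes without a single gene symbol, 7 were called after anti-IL-15 and 114 with the control antibody, and 0 by limma for the difference between the arms and after treatment.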
